A study of Danio rerio with 3 samples.

How the data were processed

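CUT&RUN was done on posterior trunk of wild-type zebrafish at 16 hours post fertilisation with antibodies against H3K27me3 (1 library) and H3K27ac (2 libraries), per the labels. Groups and replicate numbers come from the sample titles. The labels do not say whether the H3K27ac replicates came from separate clutches of embryos, so the spread between them may be technical. Control libraries were not used here.

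The submitters' processing notes name cutadapt 4.1, Bowtie2 2.4.5, SAMtools 1.16.1, Picard 3.0.0, bedtools 2.30.0 and MACS2 2.2.7.1 and the build danRer11, with no role or order. Settings of the aligner, the duplicate filter and the peak caller are not given in the sources used here. Each library has its own peak list, so peaks were not called on pooled replicates as far as the deposited lists show. For each peak the deposited lists give the fold (a ratio of pileup to local background at the summit), a p-value and a q-value as -log10, and a score, which is the authors' -log10 q times 10 cut to a whole number. The lowest -log10 q was 1.30 in each list, the value of a threshold of 0.05. The shortest region was 200 bp.

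Several summits in 1 interval stand on separate lines with the same bounds, so 25131, 56370 and 81487 lines of H3K27me3 and H3K27ac replicates 1 and 2 were merged into regions where intervals touched or overlapped. A region keeps its highest -log10 q, fold, pileup and window tags. The mitochondrial genome, which carries no histones, was left out of all comparisons, and unplaced scaffolds were kept. The deposited fold and score describe or rank regions within a list only.

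MACS2 computes fold as (pileup + 1) / (background + 1) and p from a Poisson distribution, so fold and p together give the pileup and the local background. Every line of the 3 lists had a solution within 0.001 on the -log10 scale. The background of every line was either 1 fixed value per list, taken as the genome-wide background, or a whole multiple of 0.02 within 0.05 of a multiple. A tag of 200 bp averaged over a 10-kb window adds 0.02, so these multiples were read as tags in the window around the summit. This reading comes from the values and from how MACS2 works, not from the labels. In 355 lines of H3K27me3 more than 1 solution was possible and the closest was taken. Even numbers of tags made up 63.3% of backgrounds above the genome-wide value in H3K27me3, 54.9% in H3K27ac replicate 1 and 53.0% in H3K27ac replicate 2, so tags are not fully independent of each other. On simulated lines with known pileup and background, the inversion recovered both in 99.7% of 4561 lines for H3K27me3. For H3K27ac replicates 1 and 2 it did so in all 4371 and 4428. These lines used the same formulas and backgrounds that the inversion had given. They test its arithmetic, and cannot test the reading of 0.02 as 1 tag in 10 kb.

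Overlap means at least 1 bp. H3K27ac found in both replicates is the intersection in bp of the regions of replicates 1 and 2. Expected overlap came from 1000 circular shifts of 1 set within each chromosome with a fixed seed, where a chromosome ends at the last region of any list. The overlap code was tested on simulated sets, with a ratio of 1.16 with no overlap planted and 15.8 with overlap planted. Shares have exact Clopper-Pearson 95% intervals, which cover counting error only, since neighbouring regions and reads without molecular identifiers are not independent. H3K27me3 domains join regions across gaps of at most 3 kb, and H3K27ac clusters join intervals across the wider gap usual for clustered enhancers. Both were ranked by bp under regions. Loci are the regions with the highest 10-kb tag density at least 200 kb apart, with the mean over both replicates for H3K27ac; this ranking was chosen after the data were examined.

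The overlap tests, the domains and clusters, the alternatives listed at the end of this paragraph and the rule for named items were fixed before the data were examined; the quintiles, the shifts of 50 to 500 kb, the removal of the 1% of regions with most pileup, the test of depth and the hox chromosomes were added later. The rule names genes at the 20 domains and 20 clusters with most bp and at the 15 regions with both marks that have the highest lower rank by -log10 q. It was applied to positions, because the gene table used here is of another assembly (GRCz12tu). That table gave only the names of the chromosomes that carry hox genes. The planned results on promoters, gene lists, hox genes, the hoxda domains and the place of peaks relative to genes need an annotation of danRer11, and were not analysed here. No test across samples was run, since it would compare 1 library of one antibody with 2 of another. Alternatives were a -log10 q of at least 5, the same number of regions from each list, a 50% reciprocal overlap, single replicates, a peak in either replicate, other gaps, and the removal of unplaced scaffolds and chromosome 4. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.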

Results

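CUT&RUN releases the DNA around an antibody-bound histone mark with a tethered nuclease, and here it was run on the posterior trunk of wild-type zebrafish at 16 hours post fertilisation. The study's title concerns a regulatory landscape of the cloaca, the common outlet of the gut and urinary ducts. H3K27ac marks active enhancers and promoters and was measured in 2 libraries (replicates 1 and 2), while H3K27me3, the mark of Polycomb repression, was measured in 1 library. The deposited lists held 45534 regions in H3K27ac replicate 1, 60427 in H3K27ac replicate 2 and 17121 in H3K27me3, without the mitochondrial genome. They covered 18.7, 27.2 and 9.05 Mb in that order. Positions are on danRer11, and no gene annotation of that build was used here, so regions are named by position.

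Read totals are not given in the sources used here. The genome-wide background that the peak caller used, recovered from the deposited fold and p-value of each peak, was 0.370 tags in H3K27me3, 0.806 in H3K27ac replicate 1 and 1.1 in H3K27ac replicate 2. On this scale the H3K27me3 library had 33.6% and H3K27ac replicate 1 had 73.2% of the depth of H3K27ac replicate 2, if all were called with the same genome size. The same inversion gave the tags in the 10-kb window around each peak, which divided by the genome-wide background is called the 10-kb tag density below. Its lowest possible value is 1, it is known only at called regions, and its size cannot be compared between antibodies. Values of H3K27me3 have no replicate.

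Among regions found in both replicates, H3K27ac density by the mean of the replicates was highest at the start of chromosome 9. A locus on chromosome 5 was higher in replicate 1 (25.9 against 25.5) and one on chromosome 3 in replicate 2 (29.2 against 28.4). Neither value was the highest of its replicate. The maximum over all regions, paired or not, was 27.7 in replicate 1 and 29.9 in replicate 2. The places of these maxima were not listed, so they may lie in the same loci. At position 1963618 on chromosome 9 the density was 26.9 ± 2.08 (SD, n = 2), from 1027 and 1564 tags. H3K27me3 peaked at position 2005873, 42.3 kb to the right, with a density of 265 from 4903 tags. The H3K27ac regions with summits between 1.93 and 1.99 Mb had a median density of 22.2 ± 0.224 (SD, n = 2). The marks were not fully apart: 4 H3K27me3 regions between 1.98 and 1.99 Mb had densities of 51.8 to 63.5, and H3K27ac regions there, at 1.98 Mb, had densities of 16.0 in replicate 1 and 18.7 in replicate 2. Among the densest H3K27me3 regions, from 2.00 to 2.01 Mb with densities of 131 to 265, no H3K27ac region was called in either replicate. Just to the left of them, near 2.00 Mb, 1 H3K27ac region in each replicate had a density of 4.78 ± 0.336 (SD, n = 2).

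The flanks of this chromosome 9 locus differed. To the left, down to 1.6 Mb, H3K27ac reached 11.6 ± 0.169 (SD, n = 2) near 1.83 Mb, and the 8 H3K27me3 regions had densities of 1 to 4.43. To the right, up to 2.34 Mb, H3K27ac reached only 3.86 ± 0.299 (SD, n = 2), at 2.13 Mb, and the 19 H3K27me3 regions reached 19.0 at 2.17 Mb. The difference in H3K27ac maxima between the flanks was larger than the spread between replicates. Further right, near 2.60 Mb, both marks rose again, to 9.65 ± 0.947 (SD, n = 2) for H3K27ac and 83.8 for H3K27me3. The bounds of these segments were chosen after the values were seen, and no test was run on them.

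**Figure D1:**
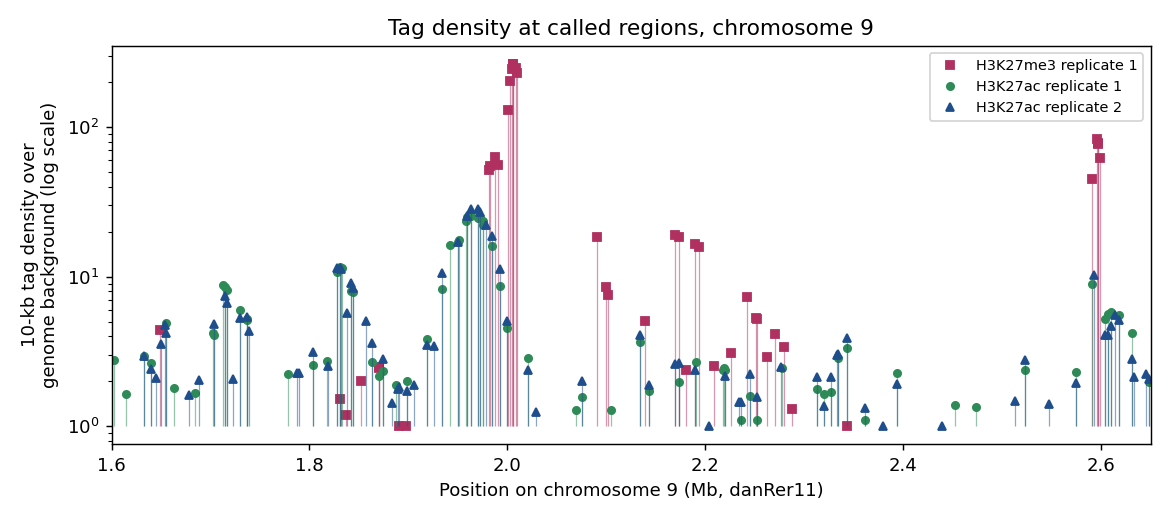
Tag density in the 10-kb window around each called region (vertical log axis, multiples of the genome-wide background) against position on chromosome 9 in Mb; each point is 1 region of 1 library and its line runs down to the background. H3K27ac reaches 25.5 and 28.4 in replicates 1 and 2 near 1.96 Mb, and H3K27me3 reaches 265 at 2.01 Mb.

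Several other loci had H3K27ac as dense as chromosome 9. The next were position 23574043 on chromosome 3 with 26.9 ± 3.23, position 32536322 on chromosome 5 with 26.2 ± 0.438, position 20913815 on chromosome 16 with 26.2 ± 2.74 and position 19753140 on chromosome 19 with 26.2 ± 1.3 (SD, n = 2 each). Position 36078427 on chromosome 23 had 26 ± 2.19 and position 2194926 on chromosome 11 had 26 ± 2.47 (SD, n = 2 each). The order of these 7 loci lies within the spread between replicates, as does the step to the next locus, at position 13287026 on chromosome 5 with 25.8 ± 1.31 (SD, n = 2). Replicate 2 was higher than replicate 1 at each of these loci. That direction was not general, since the median log2 ratio of replicate 2 over replicate 1 was 0.02 across the 27008 paired regions. The order also changed between replicates. Position 32536322 on chromosome 5 was the highest of the 7 in replicate 1 (25.9) and the lowest in replicate 2 (26.5). The 7 loci differed in H3K27me3 within 100 kb, which reached 188 on chromosome 3, 81.4 on chromosome 16, 292 on chromosome 19, 217 on chromosome 23 and 151 on chromosome 11, against 1.40 on chromosome 5. Among the other 19 of the 25 densest loci, chromosome 5 included, the highest H3K27me3 value within 100 kb was 31.2.

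**Figure D2:**
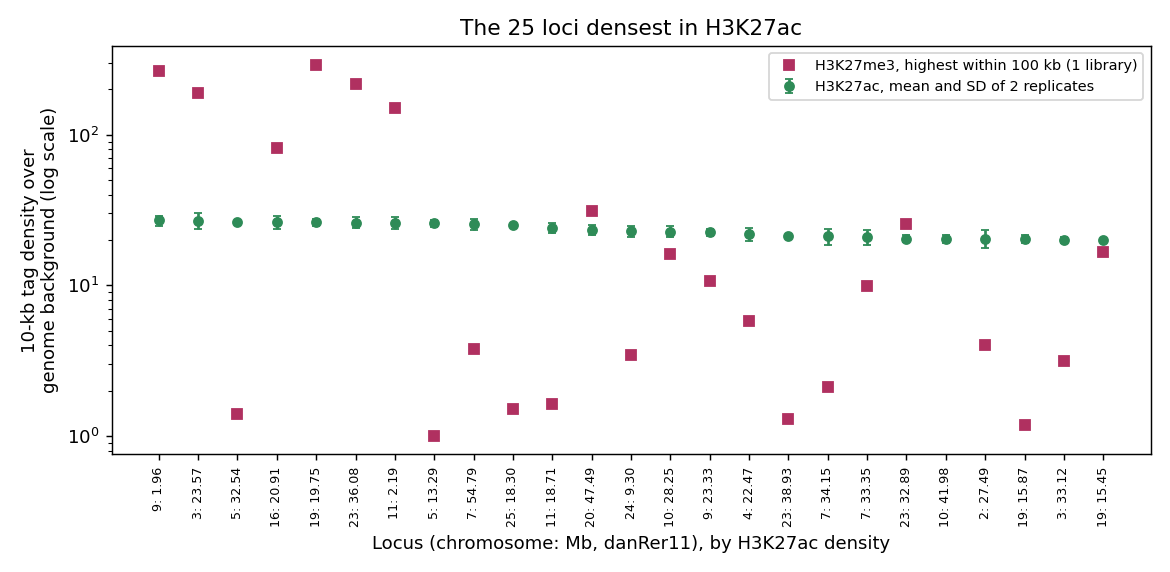
The 25 loci densest in H3K27ac in order along the horizontal axis, with the 10-kb tag density on a log axis; circles with bars give the mean and SD of the 2 H3K27ac replicates, and squares the highest H3K27me3 density within 100 kb in the single library. H3K27me3 is 81.4 to 292 at 6 loci and at most 31.2 at the others; 1 locus on chromosome 10 has no H3K27me3 region in reach and no square.

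H3K27me3 was densest elsewhere. The highest values were 413 at position 29768524 on chromosome 13, 318 at position 4978917 on chromosome 24, 315 at position 27363204 on chromosome 15 and 314 at position 35513292 on chromosome 7. Of the 25 densest H3K27me3 loci, 10 had no H3K27ac region of either replicate within 5 kb. The highest H3K27ac density within that distance of the others was 8.63, in replicate 1, where the median over all regions was 3.13. How many places taken at random would have no such region was not computed. The locus at position 19719494 on chromosome 19, with 292, was the eighth and that on chromosome 9 was number 21. The window density is part of the background against which a peak is scored, so fold fell with density in the H3K27me3 list (Spearman rho -0.48 across 17121 regions, which are not independent).

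Joined across gaps of at most 3 kb, the H3K27me3 regions formed 12932 domains, of which 154 held at least 5 regions. The domain with most bp under regions lay on chromosome 21 from 7452017 to 7470989, with 6801 bp in 8 regions and a density of up to 181. The next were on chromosome 17 from 21779970 to 21796288 with 5612 bp and on chromosome 2 from 708978 to 722333 with 5411 bp. Of the 20 domains with most bp, 14 held no interval of H3K27ac found in both replicates between their ends, gaps included. In each of the other 6 such intervals measured at most 450 bp in total. How many random stretches of these lengths would hold none was not computed. The count of domains with at least 5 regions was 20 with gaps of at most 1 kb and 405 with gaps of at most 10 kb. Ranking by bp and by density named different places, since 2 of the 20 domains held a locus among the 20 densest.

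H3K27ac found in both replicates formed 16746 clusters, of which 532 held at least 5 intervals. The cluster with most bp lay on chromosome 5 from 32504915 to 32607858, with 9814 bp in 22 intervals and a density of up to 26.2 ± 0.438 (SD, n = 2); its only H3K27me3 region had a density of 1.08. A cluster on chromosome 17 from 37682989 to 37765922 held 7787 bp, reached 19.9 ± 0.749 (SD, n = 2) and had no H3K27me3 region. The longest of the clusters, on chromosome 21 from 37111214 to 37228020, spanned 117 kb, reached 12.2 ± 0.297 (SD, n = 2) and held 17 H3K27me3 regions with densities of up to 47.7. Of the 20 clusters with most bp, 8 held no H3K27me3 region and 6 held one with a density over 10. Neither count was set against random stretches of the same lengths. The count with at least 5 intervals was 1275 without H3K27ac replicate 2, 2193 without H3K27ac replicate 1 and 3660 with a peak in either replicate. It was 37 with gaps of at most 5 kb, 29 with a -log10 q of at least 5 and 45 with the same number of regions from each list.

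H3K27ac and H3K27me3 overlapped more often than placement by chance gives. Intervals of H3K27ac found in both replicates shared 509634 bp with H3K27me3, which is 4.39% of their 11.6 Mb and 5.63% of the H3K27me3 bp. The ratio to the median of 1000 circular shifts was 6.37, with a range of 5.61 to 7.34 over the central 95% of shifts. Of the 27647 intervals, 2074 (7.50%) overlapped an H3K27me3 region, against 1.19% after shifting. Restricted to peaks with a -log10 q of at least 5, the ratio was 2.91. For comparison, the H3K27ac replicates shared 29.3 times as many bp with each other as after shifts.

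H3K27me3 summits inside H3K27ac regions were least common where H3K27me3 tags were densest. In the lowest quintile of H3K27me3 regions by 10-kb tags, 15.8% of summits lay in H3K27ac found in both replicates (exact 95% interval 14.6 to 17.1%, 542 of 3425). In the highest quintile it was 4.0% (exact 95% interval 3.37 to 4.71%, 137 of 3424). The shares were 10.2, 7.21 and 6.54% in the quintiles between them. The lowest and highest quintiles had 25 and 10.3% without H3K27ac replicate 1, 19.9 and 7.01% without H3K27ac replicate 2, and 15.4 and 2.63% with a -log10 q of at least 5. When regions were ranked by -log10 q instead, the shares from the lowest to the highest quintile were 7.36, 10.3, 10.2, 9.61 and 6.34%, with overlapping intervals at the ends and higher ones between. Across the 2030 paired regions with both marks, the H3K27me3 summit lay a median of 129 bp from the summit of H3K27ac replicate 2, and the summits of the H3K27ac replicates lay 72.5 bp apart. These regions were chosen because they overlap, and median widths in the lists were 340 to 388 bp, so short distances follow largely from the choice. No distance after shifting was computed.

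**Figure D3:**
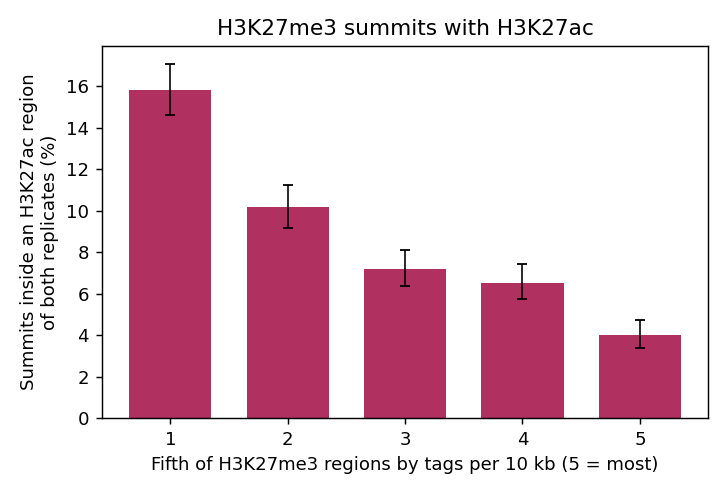
Percent of H3K27me3 summits inside H3K27ac regions found in both replicates (vertical axis) in equal groups of H3K27me3 regions by tags per 10 kb, from fewest (1) to most (5); bars are shares in 1 H3K27me3 library and lines are exact 95% intervals. The share is 15.8% in group 1 and 4.0% in group 5, against 25 and 10.3% without H3K27ac replicate 1 and 19.9 and 7.01% without replicate 2.

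By the lower of their ranks by -log10 q in the lists, the first regions with both marks were on chromosome 17 from 53383423 to 53383883 and on chromosome 4 from 63365121 to 63365392. The deposited folds were 12.1 and 17.1 in H3K27ac replicates 1 and 2 and 9.97 in H3K27me3 on chromosome 17, and 11.6, 24.3 and 28.4 on chromosome 4. On chromosome 4 the summit pileup of H3K27me3 was 66, or 97.1% of the 68 tags in its window. H3K27ac density there was 1 in both replicates, with summit pileups of 20 and 50 in replicates 1 and 2. A density of 1 in replicate 2 means at most 55.0 tags in the window, so most of them lay at the summit. None of the other 14 regions listed by this rank had more than 34.1% of its H3K27me3 window tags at the summit. The share was not computed for H3K27ac at these 14 regions, so stacks of H3K27ac reads there are not excluded. On chromosome 17 the H3K27ac summit pileup was 40 and 84 in replicates 1 and 2, at densities of 2.98 and 3.62. A region on chromosome 24 from 17260261 to 17260711 lay in a window with an H3K27me3 density of 218 and H3K27ac densities of 6.67 and 7.36. On chromosome 3, from 18567443 to 18567974, these values were 160, 4.44 and 4.74.

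The strongest H3K27ac regions were found in both replicates and the weakest in 1. Of the regions of replicate 1, 27008 of 45534 overlapped a region of replicate 2 by at least 1 bp, or 59.3% (exact 95% interval 58.9 to 59.8%), against 3.91% after shifting. Of the regions of replicate 2, 25965 of 60427 overlapped replicate 1, or 43.0% (exact 95% interval 42.6 to 43.4%), against 2.94% after shifting. In the highest quintile by -log10 q the shares were 97.6% for replicate 1 and 94.3% for replicate 2, and in the lowest 28.3 and 11.1%. With the same number of regions taken from each list, the shares over all of them were 70.5% for replicate 1 and 68.7% for replicate 2. At the 27008 paired regions the 10-kb tag density had a Spearman rho of 0.96 between replicates and the deposited fold 0.60, across regions that are not independent replicates. The log2 ratio of the densities, replicate 2 over replicate 1, had a median of 0.02 and an SD of 0.26.

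**Figure D4:**
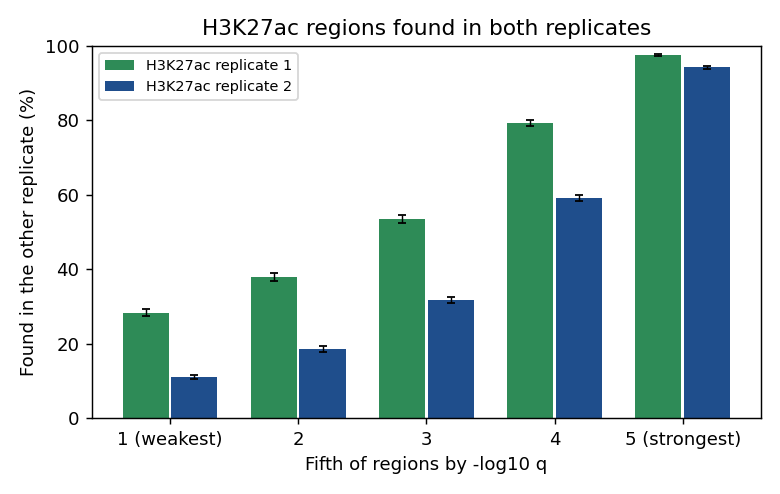
Percent of H3K27ac regions that overlap a region of the other replicate (vertical axis) in equal groups by -log10 q, from weakest (1) to strongest (5); bars are 1 replicate each and lines are exact 95% intervals. The share rises from 28.3 to 97.6% in replicate 1 and from 11.1 to 94.3% in replicate 2.

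Along the chromosomes, chromosome 4 held the fewest regions per Mb. It had 6.2 H3K27me3 regions per Mb, against 10.2 to 18.5 on the other chromosomes, and 16.7 and 23.9 per Mb in H3K27ac replicates 1 and 2, against at least 29.4 and 41.6 elsewhere. The lowest values were between 30 and 70 Mb, with 1.02 H3K27me3 regions per Mb against 14.0 in the first 30 Mb of the chromosome. H3K27ac had 2.85 against 35.8 per Mb in replicate 1 and 5.33 against 49.3 in replicate 2. From 70 Mb to the last region at 78.0 Mb there were 2.86 H3K27me3 regions per Mb and 14.7 and 21.7 H3K27ac regions per Mb in replicates 1 and 2, also below every other chromosome. This arm is rich in repeats, where short reads are hard to place, and read placement was not analysed here.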

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

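The mitochondrial genome, which was left out of the comparisons and carries no histones, held called regions in each list. There were 4 regions in H3K27me3, 4 in H3K27ac replicate 1 and 4 in H3K27ac replicate 2. They covered 22.5, 12.2 and 7.63% of its length, with the highest deposited folds at 2.99, 2.68 and 2.04. The 10-kb tag density there reached 212, 70.3 and 23.1, so the H3K27ac replicates differed by more there than at their shared nuclear regions, where the log2 ratio had an SD of 0.26. No biological explanation was tested.

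The overlap of H3K27ac with H3K27me3 was weighed against 3 technical explanations, with tests fixed before their results were seen, except the rankings by -log10 q and pileup and the shifts of single quintiles. Shifts of only 50 to 500 kb left a ratio of 5.65, which argues against shared megabases as the whole cause. Removing unplaced scaffolds, chromosome 4 and the 1% of regions with most pileup left 6.65, so the overlap did not rest on these. This cannot decide on high-copy sequence elsewhere, since H3K27me3 pileup mostly followed window tags (Spearman rho 0.95). The chromosome 4 region with 97.1% of its H3K27me3 tags at the summit had a pileup of 66, below the median of 78 in the highest pileup quintile. Cutting of open chromatin whatever the antibody could give both marks at 1 place, and then the overlap should lie where H3K27me3 is sparse: 15.8% of summits lay in H3K27ac in the quintile with fewest H3K27me3 tags and 4.0% in that with most (25 and 10.3% without H3K27ac replicate 1, 19.9 and 7.01% without replicate 2). Ranking by summit pileup kept most of this difference (12.9 and 4.38%) and ranking by -log10 q removed most of it (7.36 and 6.34%), while against shifts the share was 16.9 times as high in the lowest quintile by tags (range 12.6 to 24.6) and 4.72 times in the highest (range 3.26 to 7.21). Open chromatin therefore stays open as a cause, as do 2 marks on 1 locus in different cells and both on 1 nucleosome, which no test here separates.

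For H3K27ac regions found in 1 replicate, the test of depth was chosen after the result was seen and that of weak regions before. A difference in depth as the whole cause would have the regions of the shallower replicate 1 found in replicate 2, and 59.3% were. Weak regions near the calling threshold remain a candidate explanation, since at least 94.3% of the strongest quintile was found in the other replicate. No biological explanation was tested.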

How the results depend on the processing

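The share of H3K27ac regions found in the other replicate, 59.3% for replicate 1 and 43.0% for replicate 2, was 79.5 and 57.6% with a -log10 q of at least 5, 70.5 and 68.7% with the same number of regions from each list, and 40.8 and 30.7% with 50% reciprocal overlap. The ratio of shared H3K27ac and H3K27me3 bp to shifts, 6.37, was 2.91 with a -log10 q of at least 5 and 5.07 with the same number of regions. It was 6.05 to 6.14 without 1 H3K27ac replicate, and stayed within the range of the shifts for a peak in either replicate, without unplaced scaffolds and chromosome 4, and in both settings added after the data were seen. The 154 H3K27me3 domains with at least 5 regions became 41 with a -log10 q of at least 5, 20 with gaps of at most 1 kb and 405 with gaps of at most 10 kb. The 532 such H3K27ac clusters became 29 with a -log10 q of at least 5, 45 with the same number of regions, 37 with gaps of at most 5 kb and 3660 with a peak in either replicate. Without 1 H3K27ac replicate they were 1275 to 2193. Stricter thresholds leave fewer regions to join, and other causes were not tested. Of 38 alternatives, 11 left the value within its interval or, for a count, within 1.5 times, and 27 moved it; 1 more, the same number of regions for H3K27me3 domains, left that list as it was and tested nothing. No paired analysis was possible because H3K27me3 has 1 library. The alternatives fixed beforehand for promoters, gene lists, hox genes, the hoxda domains and the place of peaks were not run, for want of an annotation of danRer11 here. The depth of the H3K27me3 library, 33.6% of H3K27ac replicate 2, limits which sparse H3K27me3 regions could be called.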

Other observations

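The tests in this part were chosen after the result was seen. H3K27ac regions in dense windows more often had an H3K27me3 region nearby, but not on top of them. In the quintile of paired H3K27ac regions with the highest density, 25.4% had an H3K27me3 region within 5 kb (exact 95% interval 24.2 to 26.6%), against 16.2% in the lowest (exact 95% interval 15.2 to 17.2%). Direct overlap did not rise with density, at 6.90% in the highest and 7.96% in the lowest quintile (exact 95% intervals 6.24 to 7.61% and 7.25 to 8.71%).

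The 7 loci with most H3K27ac tags lay on 6 different chromosomes of the 7 that carry hox clusters (3, 9, 11, 12, 16, 19 and 23 by the gene table of GRCz12tu), with 1 on chromosome 5. A hypothesis is that these 6 loci are hox clusters, which may carry both marks in a trunk that mixes cells with different hox genes active, a mixture that was not tested. A share of 0.00016 of random draws gave as many. This is no support for the hypothesis, because the ranking and the number of loci were chosen after this pattern was seen. The next 3 loci, on chromosomes 5, 7 and 25 with densities of 25.8, 25.3 and 25.1, also lie within the SD of 2.47 of the last of the 7. Replicate 2 was the higher at that locus and at these 3, while the median log2 ratio over all paired regions was 0.02. Within replicates these 3 had 24.9, 23.8 and 24.6 against 24.3 in replicate 1, and 26.7, 26.8 and 25.5 against 27.8 in replicate 2. Stacks of reads at 1 repeat are argued against by the median of 5.11% of the window's tags at the summit, with 7.26% at most. The count was 6 without H3K27ac replicate 1, 6 without H3K27ac replicate 2 and 5 with a -log10 q of at least 5, but 2 when ranked by summit pileup and 1 when ranked by fold, which is below the mean of 1.80 over the draws, and the hypothesis stays open, as no danRer11 position of a hox gene was used here.

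The region with both marks that begins at the first base of the unplaced scaffold Un_KN149861v1 had deposited folds of 18.7 and 16.3 in H3K27ac and 10.4 in H3K27me3. Its fold and its summit pileup of 78 in H3K27ac replicate 1 were the maxima of that list. The 10-kb tag densities were 3.99 and 2.54 in H3K27ac replicates 1 and 2 and 4.86 in H3K27me3. Part of the window lies beyond the end of the scaffold and can hold no tags, which lowers these densities. Whether reads stack on a repeat there was not tested.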
